A study of Mus musculus with 8 samples.

How the data were processed

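ChIP-seq was measured in 8 samples of mouse embryonic fibroblasts, 4 ChIP samples (PEG3 and H3K9me3 antibodies in Peg3 wild-type and knockout cells) and 4 input samples, with 1 sample per group. Per the labels, the inputs listed for both antibodies of a genotype are the same raw data. The peak tables of the 4 ChIP samples were analysed here. Reads were aligned with Bowtie2 to mm10 and handled with SAMtools, per the submitters' processing notes, which give no versions. Peaks were called by the authors in each ChIP sample against the input of its genotype with MACS2 2.2.6 at a q threshold of 0.05, per the file headers. Per the file headers, 1 tag was kept per position, the larger of ChIP and input was scaled down to the smaller, and the fragment length used was 104, 99, 97 and 98 bp for wild-type PEG3, knockout PEG3, wild-type H3K9me3 and knockout H3K9me3, close to the tag size of 100 bp. The deposited tables give for each peak the pileup signal at its summit, the fold enrichment (pileup over local input background, 1 added to both), and the −log10 p-value and −log10 q-value. The header names of the last pair of columns were lost in the deposited tables, and the columns were identified from their values. Because only listed peaks have values, a site outside a list has no height.

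The fold and score arithmetic of the peak caller was checked by recomputing −log10 p from the pileup and the background behind the fold with a Poisson distribution. The largest difference was 0.00335. The fragments over the summit (pileup divided by the ChIP scale) and the input background were recovered in this way. With 1 tag per position and strand, at most 208, 198, 194 and 196 fragments can cover a base in these libraries, in the order above. The input scale was 0.880 for wild-type PEG3 and 0.642 for knockout PEG3.

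Peaks were shared if they overlapped by at least 1 bp. Shares have exact Clopper-Pearson intervals, which describe the listed peaks. Wild-type and knockout heights were compared as fragments divided by kept tags (depth-normalised) with exact conditional intervals, medians with order-statistic intervals. These ratios were not corrected for the fragment length used in each library. The pair for a peak with several partners was the highest partner, and pooled ratios count each knockout peak once. The 2 inputs and 4 ChIP libraries limit precision to counting error, and peaks are not replicates, so no test was made. Random placements (1000 for overlaps, 200 for gene ends, 100 for gene lists) kept each peak's length and chromosome, up to the last listed gene or peak. The probability of listing in the other genotype took the observed depth-normalised height as the expected one, scaled it to the other library, and asked how often a Poisson count passes the lowest listed −log10 p there. The recovered input background of the peak was carried over in the same way, and scaled heights above the ceiling of the other library were set to that ceiling. Overlap and interval functions were tested on simulated lists, in which 50 of 50 planted PEG3 overlaps and 57 of 57 planted H3K9me3 overlaps were recovered, and intervals covered a known ratio in 487 of 500 simulated pairs.

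Gene positions came from a RefSeq table of the same build (49980 genes with a position, 21900 protein-coding), which gives neither strand nor exons. The planned classes of promoter, exon and intron were therefore replaced by the distance from the summit to either end of a protein-coding gene (1 kb) and the gene body, and the nearest gene end replaced the nearest transcription start. Named peaks followed a rule set before the data were examined. Per antibody it takes the 10 highest-fold peaks of wild type alone, the 10 of knockout alone and the 5 highest shared ones (the rule did not say whose fold ranks them, and wild-type fold was used), with the gene each lies in or the nearest within 50 kb, and every gene of the 18 fixed lists with a peak within 10 kb. Predicted genes are given by position. Alternatives set in advance were a reciprocal overlap, a 1000 bp gap, a stricter q, upper parts of the lists by fold, leaving out the Y chromosome or peaks of the other antibody, other distances to genes and scaled folds. Leaving out peaks at the ceiling, the Peg3 gene or both sex chromosomes, merging peaks within 10 kb, depth-normalised fragments in place of the fold, ranking shared peaks by knockout fold, and leaving out background values at the genome-wide floor of the caller were chosen after seeing the data. Scripts used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.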

Results

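Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on mouse embryonic fibroblasts, primary connective-tissue cells taken from embryos at 14.5 days post coitum. The cells were wild type or knockout for Peg3, an imprinted gene that encodes a DNA-binding zinc finger protein. Each genotype gave 1 library with an antibody against PEG3 and 1 library with an antibody against H3K9me3, the trimethylated form of histone H3 lysine 9 that marks silent chromatin. The wild-type PEG3 library kept 21396407 tags and the knockout PEG3 library 16986250. The wild-type and knockout H3K9me3 libraries kept 26295696 and 27289192 tags, and the inputs of the 2 genotypes 24305045 and 26470256. The peak lists held 152 wild-type and 163 knockout PEG3 peaks, and 173 wild-type and 93 knockout H3K9me3 peaks. With 1 library per group no difference between genotypes could be tested against replicate error, and no p-value is given. Intervals are 95% intervals. Those for ratios of fragment counts (exact conditional) cover counting error only. Those for shares of listed peaks (exact Clopper-Pearson) and those of medians (order statistics over the peaks) treat peaks of the same cluster as independent. Folds are the authors' values per peak.

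The targeted gene was examined first. Peg3 (chromosome 7, 6703892 to 6730462, mm10) carried 13 PEG3 antibody peaks in wild type and 19 in knockout cells. The longest peak was 4250 bp in wild type (6707476 to 6711725), with 58 fragments over the summit and a 26.9-fold enrichment, and 4339 bp in knockout, with 61 fragments and a 32.6-fold enrichment. In the gene 11 wild-type peaks overlapped a knockout peak, and 2 of them met the same one. With each knockout peak counted once, the fragments of 10 pairs came to 229 in wild type and 220 in knockout, a depth-normalised knockout over wild-type ratio of 1.21 (interval 1.001 to 1.46). H3K9me3 peaks in the gene numbered 2 in wild type, the higher with 14 fragments, and 0 in knockout. The peak lists thus show no loss of PEG3 antibody signal at Peg3 in the knockout, and they do not show whether the protein was absent.

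**Figure D1:**
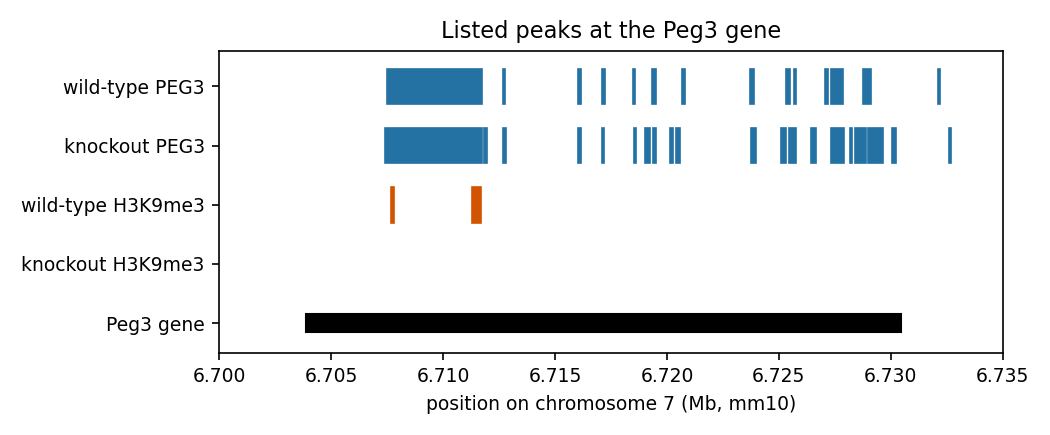
Position of every listed peak on chromosome 7 around Peg3 (horizontal, position in Mb), 1 row per library, with the extent of the gene as a black bar. PEG3 antibody peaks tile the gene in both genotypes (13 in wild type, 19 in knockout), and H3K9me3 peaks number 2 in wild type and 0 in knockout.

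The first comparison asked where the PEG3 antibody enriched DNA in wild-type and not in knockout cells. Among the 10 highest peaks listed in wild type alone, 9 lay in or near a named gene. They lay in Anks6 (10.5-fold, 22 fragments), in Rara, the retinoic acid receptor alpha (8.96-fold, 26 fragments), and 183 bp outside Msl3, a subunit of a histone acetyltransferase complex (8.33-fold, 22 fragments). Others lay in Pam, an enzyme of peptide amidation (8.21-fold), in Npffr1, a neuropeptide receptor (8.01-fold), and in Il1r1, the interleukin 1 receptor (7.63-fold). The peak at 142580345 to 142580775 on chromosome 7 lay 2409 bp outside H19, an imprinted noncoding RNA gene (7.69-fold, 27 fragments). The remaining named ones lay 10606 bp outside Slc35f2 (7.31-fold) and 82 bp outside Brsk1 (7.31-fold), and the unnamed one lay on chromosome 16 at 45353018 (9.34-fold). Among the 10 highest peaks of knockout alone, 2 lay in Peg3 itself (12.1-fold and 7.90-fold) and 2 in Aebp2, a cofactor of Polycomb complexes (7.88-fold and 7.37-fold). Single ones lay in Marchf1, a ubiquitin ligase gene (20.5-fold, 38 fragments), Kcnip1 (9.23-fold), Smo, the Hedgehog signal transducer (8.95-fold), and Cdc27, a subunit of the anaphase-promoting complex (8.93-fold), and 2 lay in or near predicted genes on chromosomes 1 (9.76-fold) and 13 (7.81-fold). Those in Smo and on chromosome 13 also overlapped an H3K9me3 peak. Peaks within 1000 bp of a PEG3 peak of the other genotype included the wild-type one outside Slc35f2 and, in knockout, those in Smo, in Peg3 and on chromosome 13. Within 1000 bp, 72 of 152 wild-type and 81 of 163 knockout PEG3 peaks had a partner in the other genotype.

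Of the 152 wild-type PEG3 peaks, 62 overlapped a knockout peak by at least 1 bp, or 40.8% (32.9% to 49.0%), and 90 were listed in wild type alone. Of the 163 knockout peaks, 65 overlapped a wild-type peak, or 39.9% (32.3% to 47.8%), and 98 were listed in knockout alone. In 1000 random placements of the wild-type peaks on their chromosomes at most 1 peak met a knockout peak. The knockout library was the shallower one. With the height of each wild-type peak held equal after depth normalisation, 64.4 of the 90 were expected to pass in the knockout library, and 17 of the 90 had a probability of at least 95%. H19, Msl3, Rara, Npffr1 and Anks6 were among these 17. In the other direction, 75.7 of the 98 peaks of knockout alone were expected to pass in the wild-type library, 53 of them with a probability of at least 95%. Peaks chosen for passing a threshold run high, which raises these numbers. Each peak's input background was carried over as well, though at shared PEG3 peaks it was lower in knockout (median ratio 0.743). Peaks at the ceiling of the duplicate filter were also scaled by depth, and gave 13.2 expected among the 27 knockout peaks at the start of chromosome 9. The numbers are therefore rough and not bounds, and they single out peaks of either genotype. Of the 98 peaks of knockout alone, 55 had a fold under 3, and 46 of these reached at least 80% of the highest pileup the authors' duplicate filter allows. Without all peaks at that ceiling the lists held 151 wild-type and 116 knockout peaks, and the shared part of the knockout list was 55.2%.

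**Figure D2:**
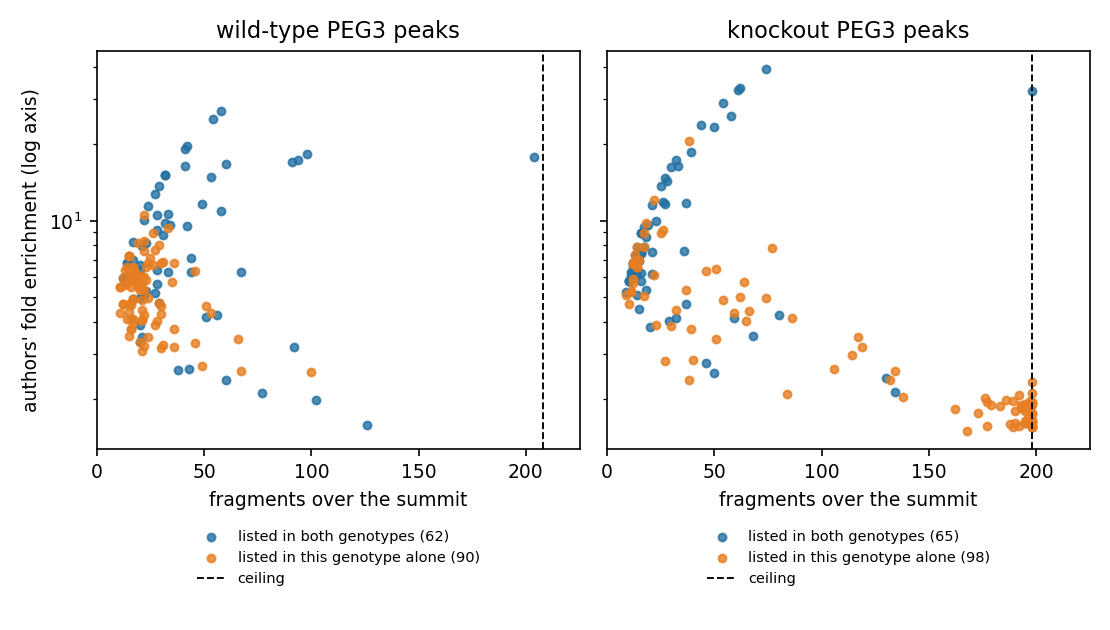
Authors' fold enrichment (log axis) against fragments over the summit for each PEG3 peak in wild type (left) and knockout (right), coloured by whether the peak was listed in both genotypes, with the ceiling of the duplicate filter dashed (208 fragments in wild type, 198 in knockout). In the knockout panel 47 peaks lie at 80% of the ceiling or above, and in the wild-type panel 1 does.

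The height of the shared PEG3 peaks differed between the genotypes by ratios that ranged from below to above 1. Chd9, which encodes a chromatin remodeller, had 94 fragments over the summit in wild type and 27 in knockout, a depth-normalised ratio of 0.362 (0.227 to 0.560). The ratio was 0.512 (0.340 to 0.758) in Cdc20b, 0.458 (0.241 to 0.828) near Plekhh3 and 0.643 (0.448 to 0.912) in Hexim1, which encodes an inhibitor of transcription elongation. It was 1.89 (1.07 to 3.40) in Cdc27, 1.91 (1.17 to 3.17) at a predicted gene on chromosome 14 at 104336940, 1.78 (1.17 to 2.73) in Ano2, which encodes a chloride channel, and 1.62 (1.06 to 2.48) at a peak on chromosome 11 at 25100074, over 50 kb from any gene. The ratio of the folds was 0.674 in Chd9, 0.692 in Cdc20b, 0.996 near Plekhh3 and 1.27 in Hexim1, so for the last pair the lower height in knockout was not seen in the fold, and at the 4 higher peaks it lay between 1.35 and 1.73. Hexim1, Ano2 and the chromosome 11 peak were among the 5 highest shared peaks by wild-type fold, with Peg3 and a peak in the immunoglobulin heavy chain locus Igh (0.583, 0.348 to 0.953). By knockout fold only Peg3 and the chromosome 11 peak stayed among the 5 highest. Chd9, Cdc20b, Plekhh3, Cdc27 and the chromosome 14 peak were chosen after their values were seen. Of the 62 shared peaks, 8 had an interval wholly below 1 and 10 an interval wholly above 1. The ratios were not corrected for the fragment length used, 104 bp in wild type and 99 bp in knockout. A longer fragment length raises the count over a summit, so intervals that end close to 1 are uncertain. Among these 10, the peak on chromosome 17 at 4626162 (204 and 198 fragments) lay at or near the duplicate ceiling in both libraries. Its ratio of 1.22 (1.0003 to 1.49) is therefore not a measured difference in height. The median depth-normalised ratio was 0.939 (0.830 to 1.19), whereas the median ratio of the authors' folds was 1.17 (1.03 to 1.29), so the direction depended on the measure. The background recovered from the folds had a median ratio of 0.743 (0.612 to 0.918), but at 25 of the 62 pairs at least 1 value was the genome-wide floor of the peak caller and not a local input value, and a pair with both at the floor gives 0.952. The other 37 pairs, a selection made after seeing the data, had a median ratio of 0.627 (0.550 to 0.801).

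**Figure D3:**
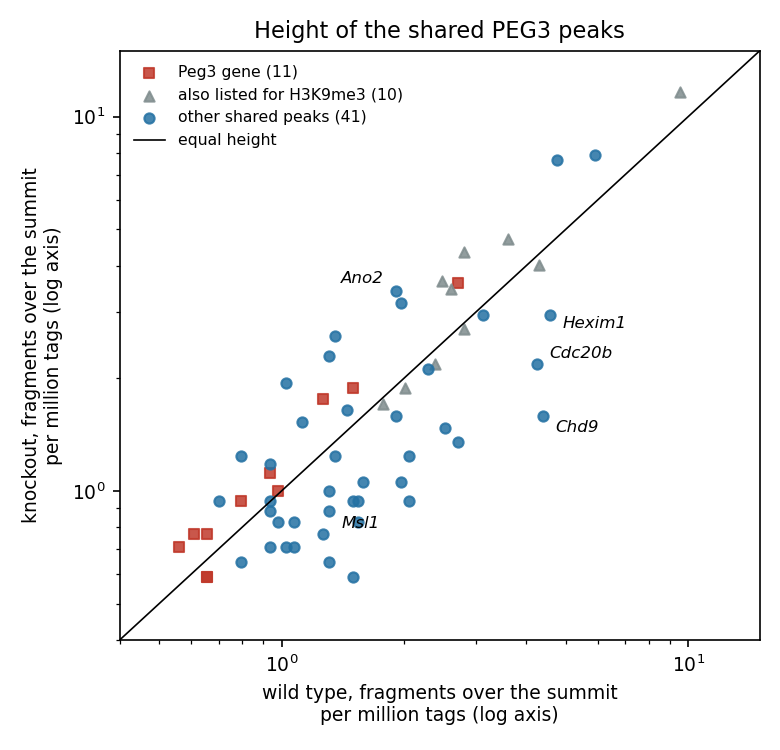
Depth-normalised fragments over the summit in wild type (horizontal, log axis) and knockout (vertical, log axis) for the 62 shared PEG3 peaks, 1 point per peak, with the line of equal height. Chd9, Cdc20b and Hexim1 lie below the line and Ano2 above it, while the 11 peaks of the Peg3 gene lie close to it.

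The part of the PEG3 peaks near the ends of genes differed between the lists. Within 1 kb of either end of a protein-coding gene lay 44 of 152 wild-type peaks, or 28.9% (21.9% to 36.8%), and 19 of 163 knockout peaks, or 11.7% (7.17% to 17.6%). Random placement gave 3.30% for the wild-type list and 3.26% for the knockout list. Of the peaks listed in wild type alone, 31 of 90 lay there, or 34.4% (24.7% to 45.2%), against 6 of 98, or 6.12% (2.28% to 12.9%), of those in knockout alone. Without the Peg3 gene, peaks of the other antibody and peaks at the ceiling, these shares were 39.5% (28.4% to 51.4%) and 12.5% (3.51% to 29.0%), whose intervals overlap. Of the shared peaks, the same sites in both lists, 13 of 62 in wild type and 13 of 65 in knockout lay there, and in the upper part of the lists by fold the shares were 26.0% and 19.5%. At the 13 shared wild-type peaks near gene ends the recovered input background was lower in knockout (median ratio 0.482, 0.343 to 0.679), and whether this bears on the shares was not tested. A further 59 wild-type and 52 knockout peaks lay deeper inside a protein-coding gene. For H3K9me3, 15 of 173 wild-type peaks (8.67%, 4.93% to 13.9%) and 2 of 93 knockout peaks (2.15%, 0.262% to 7.55%) lay within 1 kb of a gene end.

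The second comparison asked how the listed H3K9me3 peaks differed between the genotypes. The 173 wild-type and 93 knockout peaks covered 36528 and 21245 bp, with median lengths of 161 and 160 bp. The comparison therefore holds for these short listed sites and not for H3K9me3 across the genome. The highest peaks listed in wild type alone lay on the Y chromosome at 12752725 (12.3-fold, 29 fragments), on chromosome 18 at 82170816 (10.2-fold), 4752 bp outside Cdkn1a, the gene of the cell cycle inhibitor p21 (9.58-fold, 30 fragments), and in Lrrk2, a protein kinase gene (9.44-fold). Others lay on the X chromosome at 170809944 (9.44-fold), in Smo (8.78-fold), 3934 bp outside the vomeronasal receptor gene Vmn1r2 (8.33-fold, 44 fragments) and in Mogat1, an acyltransferase gene (7.64-fold), and the other 2 lay 9296 bp outside a predicted gene on chromosome 19 (9.03-fold) and in one on chromosome 1 (7.80-fold). The peaks on chromosome 18, near Cdkn1a, in Smo and in Mogat1 lay within 1000 bp of a knockout H3K9me3 peak without overlapping it. Within 1000 bp, 91 of the 173 wild-type and 74 of the 93 knockout peaks had a partner in the other genotype. The highest peaks of knockout alone lay 3309 bp outside the vomeronasal receptor pseudogene Vmn1r-ps47 (10.2-fold, 24 fragments), in a predicted gene on chromosome 6 (8.14-fold), 18046 bp outside one on chromosome 5 (7.87-fold), on chromosome 1 at 190300492 (7.77-fold, over 50 kb from any gene) and 179 bp outside a predicted gene on chromosome 8 (6.58-fold). They were followed by peaks 4784 bp outside Dcdc2a (6.11-fold), 22370 bp outside Vmn1r-ps2 (6.11-fold), 2166 bp outside the zinc finger pseudogene Znf41-ps (5.97-fold), 57 bp outside a predicted gene on chromosome 12 (5.83-fold) and 11317 bp outside Eci2 (5.83-fold). The shared peaks with the highest wild-type fold lay 5567 bp outside Aadac (12.2-fold), on chromosome 16 at 3236045 (11.5-fold), in Dlgap2 (10.4-fold) and in predicted genes on chromosomes 11 (9.58-fold) and 17 (9.53-fold). Only the chromosome 16 peak was also among the 5 highest by knockout fold.

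Of the 173 wild-type H3K9me3 peaks 66 overlapped a knockout peak, or 38.2% (30.9% to 45.8%), and 107 were listed in wild type alone. Of the 93 knockout peaks 67 overlapped a wild-type peak, or 72.0% (61.8% to 80.9%), and 26 were listed in knockout alone. Random placement of the wild-type peaks gave at most 1 overlap in 1000 draws. The knockout library was the deeper one, and at equal depth-normalised height and background 86.5 of the 107 were expected to pass there. In the other direction it was 23.2 of the 26 peaks of knockout alone, and both numbers are as rough as those for PEG3. Shared peaks passed in both libraries by definition, and their median depth-normalised ratio was 0.900 (0.847 to 0.974), and 47 of 66 peaks were lower in knockout, of which 7 had an interval wholly below 1. Of the 19 higher peaks 4 had an interval wholly above 1, and 3 of these lay on the Y chromosome. The 28 shared peaks also listed with the PEG3 antibody had a median ratio of 0.865 (0.798 to 0.922), and 25 of them were lower in knockout. Of the others, the 17 over 200 bp long in wild type had a median of 0.972 (0.808 to 1.04), with 11 lower. The 21 shorter ones had a median of 0.997 (0.841 to 1.12), with 11 lower. The median ratio of the folds was 0.949 (0.835 to 1.09).

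Of the 107 peaks listed in wild type alone, 41 lay in 4 regions, which were chosen after their values were seen. Between Cdkn1a and Rab44 on chromosome 17 (29102865 to 29108521) wild type had 11 peaks and knockout 3. At the repeated Duxf3 homeobox genes on chromosome 10 (58221728 to 58239656) the numbers were 13 and 6. In a window on chromosome 8 (55117110 to 55383090), which holds predicted genes, wild type had 14 peaks and knockout 1, with 15 to 33 fragments over the wild-type summits. On the X chromosome from 169989686 to 170843806 wild type had 10 peaks and knockout 0. The labels used here do not give the sex of the embryos, and the input background at the 4 shared Y peaks was higher in knockout (median ratio 2.80, range 2.14 to 5.64). Counts on Y are therefore not separable from a difference in sex between the cell pools. The knockout list held 0 H3K9me3 peaks on X, so the input there could not be compared. With the PEG3 antibody, this X region had 1 peak in wild type (66 fragments) and 0 in knockout, so the contrast was not particular to H3K9me3. Whether a difference in sex bears on this X region was not tested. Regions around Tmem267 (11 and 8), at 3109562 on chromosome 10 (12 and 11) and at 74528695 on chromosome 13 (6 and 6) differed less. When peaks within 10 kb were merged across the genotypes, H3K9me3 formed 96 regions, of which 34 had peaks in both genotypes, 48 in wild type alone and 14 in knockout alone.

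**Figure D4:**
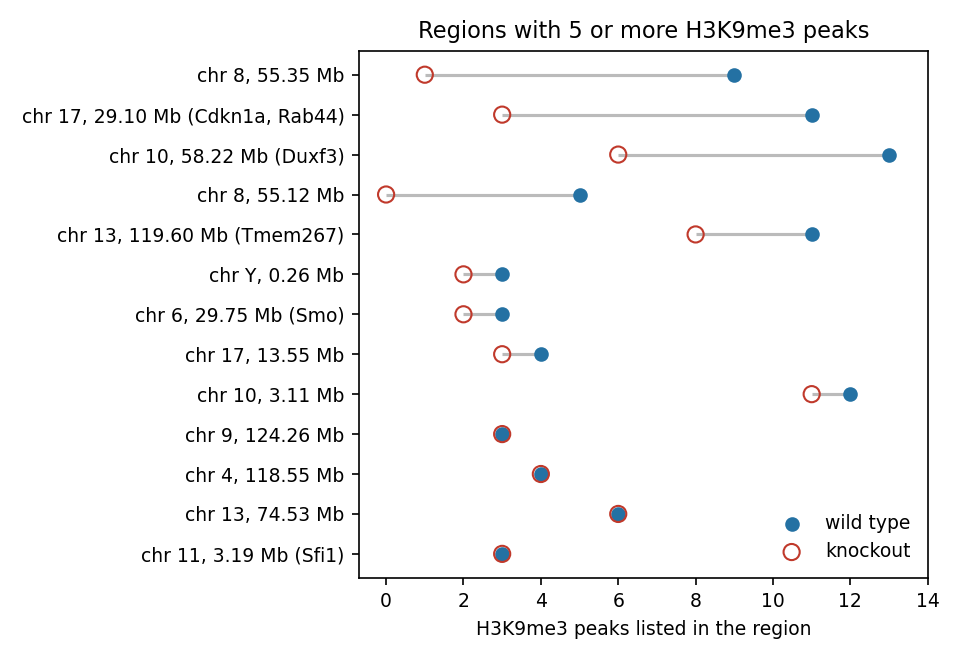
Number of H3K9me3 peaks listed in wild type (filled) and knockout (open) in each of the 13 regions that hold at least 5 peaks when peaks within 10 kb are merged, named by chromosome and start. The regions at Cdkn1a and Rab44 (11 and 3), Duxf3 (13 and 6) and both regions on chromosome 8 (9 and 1, 5 and 0) stand apart, and the others differ by 3 peaks or fewer.

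The third comparison set both antibodies side by side within a genotype. Of the wild-type PEG3 peaks 23 of 152 overlapped a wild-type H3K9me3 peak, or 15.1% (9.84% to 21.8%), and of the knockout PEG3 peaks 21 of 163 overlapped a knockout H3K9me3 peak, or 12.9% (8.16% to 19.02%). Random placement gave at most 1. Those in Smo, Tmem267 and Dpp9 and in unnamed clusters on chromosomes 10, 13 and 17 were found in both genotypes. Among the overlaps found in wild type alone were those in Sos2, Dlgap2 and Peg3 and near Aadac, and among those found in knockout alone was 1 at Duxf3. A region listed for both antibodies in the knockout was not separable from antibody-independent enrichment. In the upper part of the PEG3 lists by fold the shares were 6.49% in wild type and 7.32% in knockout.

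Genes of the fixed lists were rarely near a peak. Among 9 PEG3 targets recalled from earlier work, a wild-type PEG3 peak lay at 3 (H19, Msl1 and Msl3) and a knockout peak at 1 (Msl1), where random placement gave a mean of 0.03 for either list. Random placement did not keep the closeness of peaks to gene ends. Within 1 kb of one lay 28.9% of wild-type and 11.7% of knockout PEG3 peaks, against 3.30% and 3.26% of placed ones. The contrast therefore does not show a preference for these targets over other genes. Msl1 had 28 fragments in wild type and 15 in knockout, a ratio of 0.675 (0.335 to 1.31). Of 6 measured genes of the Peg3 domain, Peg3, Peg3os and Usp29 had PEG3 peaks in both genotypes, and 2 had H3K9me3 peaks in wild type. These genes lie close together and the hits are the same peaks, in all 14 wild-type and 20 knockout PEG3 peaks and 2 wild-type H3K9me3 peaks within 10 kb of Peg3. Of 68 imprinted genes, 3 had a wild-type PEG3 peak (H19, Peg3 and Usp29), 2 a knockout PEG3 peak, 1 a wild-type H3K9me3 peak and 0 a knockout one, and all but the H19 peak are again those near Peg3. These counts lay within the range of random placement, which gave up to 4 genes for either PEG3 list and up to 3 for either H3K9me3 list. Of 494 zinc finger genes, Zfp629 had PEG3 peaks in both genotypes and Zfp41 in wild type, and Zfp978, Zfp988 and Zfp991 had H3K9me3 peaks in wild type alone, 3 peaks in all. Random placement gave up to 5 zinc finger genes for either wild-type list, so these counts too lay within its range. Of 359 vomeronasal receptor genes, 4 had a wild-type H3K9me3 peak (Vmn1r2, Vmn1r3, Vmn1r238 and Vmn2r125) and 2 a knockout one (Vmn1r66 and Vmn2r125), where random placement gave up to 3 and up to 2. The peak at Vmn1r3 (chromosome 4, 3176864 to 3176992) was also 1 of the 2 at Vmn1r2, and all peaks at these genes lay outside the gene, by 1504 to 9695 bp. None of the 4 lists had a peak at a gene of the H3K9me3 machinery, fibroblast, endothelial, macrophage, epithelial, neural, muscle, lipid metabolism, olfactory receptor, protocadherin, histone, prolactin or Hox lists.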

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

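All tests in this part were chosen after the result was seen. The number of listed peaks moved in opposite directions between the genotypes for the 2 antibodies. PEG3 peaks were 11 more in knockout (152 and 163), and H3K9me3 peaks fell by 80 (173 and 93). The difference was not tested, since each value is from 1 library. Without peaks at the duplicate ceiling the PEG3 lists held 151 and 116 peaks, so the PEG3 direction turned.

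The excess of PEG3 peaks in knockout alone rests on low folds at sites such as the start of chromosome 9, where 27 knockout peaks and 0 wild-type peaks lay between 3000323 and 3038234. The authors kept 1 tag per position, which caps a pileup at 198 fragments in the knockout library. The input was then scaled by 0.642 in knockout and by 0.880 in wild type. A site at the cap in ChIP and input would thereby score a −log10 p of 8.65 in knockout, above the lowest listed value of 6.48, and 1.49 in wild type, below its lowest listed value of 6.00. Of the 55 with a fold under 3, 83.6% lay at 80% of the cap or above in ChIP. Among all knockout PEG3 peaks 47 did so, and 12 had a background near the cap of the input. The cutoff for the input was stricter than 80% of its cap, so the 47 and the 12 are not like counts. Unequal depth under this filter may account for part of these peaks, and how large a part was not determined. More PEG3 antibody signal at these sites in knockout cells stays open, since 1 of the 9 peaks below the cap had a wild-type height within 1000 bp.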

How the results depend on the processing

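Of 104 alternative values for 24 results, 64 stayed within the 95% interval of the reported value (for counts of genes or peaks, within 1.5 times of it) and 40 did not; the cause was not tested. With a 50% reciprocal overlap the shared part was 26.3% of wild-type and 24.5% of knockout PEG3 peaks, and 7.89% and 7.36% of them overlapped H3K9me3. Within 1000 bp it was 49.7% of knockout PEG3 and 52.6% of wild-type H3K9me3 peaks, and with the stricter q 50.9% of wild-type H3K9me3 peaks. In the upper part (from the median) of both lists by fold it was 51.9% and 51.2% for PEG3 and 24.1% and 42.6% for H3K9me3 (wild type, then knockout), and against a whole second list 54.5% and 64.6% for PEG3. The overlap of PEG3 with H3K9me3 was 6.49% and 7.32% in either case. Without peaks of the other antibody, 27.1% and 61.5% of H3K9me3 peaks were shared. The alternatives added after seeing the data gave 55.2% of knockout PEG3 peaks without the ceiling, and with merged peaks 56.0% for knockout PEG3 and 60.4% for knockout H3K9me3. Ranked by knockout fold, 2 PEG3 and 1 H3K9me3 of the 5 shared peaks named by wild-type fold stayed among the 5 highest. The median PEG3 fold ratio was 1.36 with folds divided by the list median, and 0.939 with depth-normalised fragments. Within 5 kb of a gene end lay 48.0% and 23.9% of PEG3 and 29.5% and 19.4% of H3K9me3 peaks, and in the upper part by fold 19.5% of knockout PEG3 (26.0% of wild-type PEG3) and 0 knockout H3K9me3 peaks lay within 1 kb. Genes of the fixed lists with a peak (8, 5, 9 and 2 for wild-type PEG3, knockout PEG3, wild-type and knockout H3K9me3) numbered 5 for wild-type PEG3, 3 and 0 for H3K9me3 with the gene body alone, 13, 8, 19 and 5 with 50 kb, and 1 for knockout H3K9me3 in the upper part by fold. No mitochondrial or unplaced peak was listed. No replicate could be left out, as each group has 1 library. No paired analysis was possible because no result comes from a test. The lowest listed peaks had 11, 9, 10 and 14 fragments for wild-type PEG3, knockout PEG3, wild-type and knockout H3K9me3, and sites with fewer are not measured.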

Other observations

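All tests in this part were chosen after the results were seen. H3K9me3 peaks on the Y chromosome stood apart from autosomal ones. The 4 shared Y peaks had a median knockout over wild-type ratio of 1.75 in depth-normalised fragments (range 1.41 to 2.06), against 0.897 at the 62 autosomal ones. The recovered input background there had a median ratio of 2.80, against 0.918, and the authors' fold ran the other way, with a median ratio of 0.595 (range 0.424 to 0.866), against 1.01. Whether the cell pools differed in sex was not analysed here, and these ratios are not separable from such a difference.

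The ratios of the shared PEG3 peaks differed from peak to peak, and 16 of 62 intervals left out the pooled ratio of 1.01. A single factor of depth or yield with counting error alone gives 3.1. With 1 library per genotype the spread between libraries is unknown, so a single factor with such spread around it stays open. Candidate explanations are that wide peaks, or peaks at gene ends, depend on Peg3, examined on the 41 shared peaks outside the Peg3 gene that were not listed for H3K9me3. Wide and narrow peaks (split at 200 bp) had median ratios of 0.657 (0.540 to 0.815) and 1.46 (0.840 to 1.78) by wild-type width, which favours peaks high in wild type, and of 0.760 (0.611 to 0.945) and 0.815 (0.583 to 1.61) by knockout width, where the pooled ratios were 0.814 (0.737 to 0.898) and 1.07 (0.948 to 1.20). Within 1 kb of a gene end and further away the medians were 0.667 (0.512 to 0.925) and 0.822 (0.611 to 1.34) and the pooled ratios 0.686 (0.595 to 0.791) and 1.02 (0.935 to 1.12), while the folds had medians of 1.25 and 1.03. The recovered input background, some of it at the caller's floor, had medians of 0.482 (0.343 to 0.679) and 0.868 (0.666 to 0.952) there. In wide and narrow peaks it had medians of 0.558 (0.400 to 0.728) and 1.01 (0.818 to 1.36) by wild-type width, and 0.582 and 0.952 by knockout width. Input uses no antibody, so lower fragment ratios at these sites do not by themselves show a change in binding. By width the folds ran the same way as the fragments, with medians of 0.916 (0.699 to 1.25) and 1.37 (1.02 to 1.73) by wild-type width and 1.03 and 1.14 by knockout width, but the intervals of the medians overlap by knockout width and both explanations stay open.

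PEG3 antibody peaks along the Peg3 gene were present in both genotypes. Binding of PEG3 protein that knockout cells lack is argued against as their source by the pooled ratio of 1.21 (1.001 to 1.46, counting error only), if the protein is absent, which the files do not show. Peg3 DNA from another source, alike in the libraries of both antibodies, is argued against, since at the amount of the knockout PEG3 library 97.0 fragments were expected over the highest peak in the knockout H3K9me3 library, where 12 are needed and 0 peaks were listed. In wild type 66.5 were expected, and the higher of 2 H3K9me3 peaks had 14. Such DNA in the PEG3 libraries alone may still be the source, and whether the peaks follow exons was not analysed here.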
